A study of Homo sapiens with 6 samples.

How the data were processed

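Gene expression was measured in A549 cells, a human lung adenocarcinoma line with epithelial features, after transfection with an siRNA against Snai1, an siRNA against the long noncoding RNA ncRNA-a7, or a control siRNA. Each of the 3 groups held 2 arrays, 6 arrays in all, and groups and replicate numbers were taken from the labels. Total RNA was labelled with biotin, per the labels, and hybridised to a single-colour Illumina HumanHT-12 V3 bead array. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

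The deposited scanner table gives 1 signal intensity per probe and array on a linear scale, not normalized. The mean intensity per array ran from 715 to 914 and the median from 147.5 to 154.1. The deposited series matrix holds the authors' values of the same arrays as linear intensity. Each of its columns equalled the scanner column multiplied by a single constant, from 0.783 to 1, which brought every array's mean to 715, with medians from 120.2 to 147.5. No log scale, centring or ratio was applied in it, and the direction of its values follows the signal. The software that produced either table is not given in the sources used here. Neither table as used here held detection p-values or negative control probes, so the background of these arrays was not measured.

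Probes were named through the platform annotation. Of 48701 probes, 28044 had 1 gene symbol, 13 had several and 20644 had none, and 18833 genes were named. Gene IDs of 28005 of the named probes were found in the RefSeq table of assembly GRCh38.p14, and 0 symbols needed updating. The array build is not named, so that table was used for names and chromosomes alone. Probes with several symbols or none were kept under their own IDs and are not named. ncRNA-a7 was looked up under TRERNA1, a name taken from general knowledge and not from the labels.

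Signals were corrected with limma's normexp method with an offset of 50, quantile normalized between arrays and put on the log2 scale. Fold changes are therefore on the log2(value + offset) scale and understate the change of dim genes. Probes with a mean log2 value above the median over probes were kept, which left 24350. A gene was represented by its probe with the highest mean, which gave 19730 features tested, made up of 13057 named genes and 6673 unnamed probes. All 6 arrays entered 1 limma fit (lmFit and eBayes, with 3 residual and 8.90 prior degrees of freedom), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The typical standard error of a log2 fold change was 0.13. Adjusted p-values in the text are limma's with Benjamini-Hochberg adjustment, over all features for genes and over 22 lists for gene lists.

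Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated for each list. The second form takes its degrees of freedom from the fit, 3 here, so its power is low. A call lost under it may reflect that alone. Fry tested whether the genes of a list moved, on balance, one way, which compares the list with no other genes. It was not run under the alternatives, and a list is called in the text by camera alone. Besides pathway and cell state lists, they include markers of fibroblasts, leukocytes and endothelial cells. Counts of list members are given over all features tested and adjusted over the list alone. Named genes followed a fixed rule: AURKA, CDH1, VIM, SNAI1 and ncRNA-a7 in every comparison, then the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the groups and whose mean lay in the upper 75% of features, then up to 3 called members of each list with the smallest p, and the 5 genes of each direction changed most in both knockdowns. Further list members named in the text were chosen after their values were seen.

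Groups, comparisons, tests, gene lists, the naming rule and the alternatives were fixed before the data were examined. The planned form for tables without detection p-values was the one used. Alternatives covered no background correction, an offset of 16, median scaling, cyclic loess, the authors' scaled values, no filter, the probes brighter than 75% of all probes, the mean of a gene's probes, a trended robust variance prior, fits of the compared groups alone, a replicate block, a minimum change of 1.5-fold and leaving out each array. With 1 array of a group left out, the lone array was assumed to vary like the other groups.

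The procedure was tested on simulated data with known changes. Of genes changed 2-fold, 80% were recovered for Snai1 siRNA against control over 19738 features, 76% for ncRNA-a7 siRNA against control over 19722 and 78% between the siRNAs over 19724. Of genes changed 1.5-fold, 36%, 46% and 20% were recovered. False calls made up 7.96%, 4.46% and 6.00% of calls. Both comparisons against control share the control arrays, so 100 data sets without change were simulated against shared controls to give the agreement expected with no effect. Groups of 2 are too small for a count of other splits of the arrays. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.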

Results

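Expression profiles were compared between 3 groups of A549 cells with 2 arrays each, in which an siRNA against Snai1, an siRNA against ncRNA-a7 or a control had been introduced. SNAI1 is a zinc finger transcription factor known to repress CDH1 during epithelial to mesenchymal transition. ncRNA-a7 is a long noncoding RNA known to be transcribed near SNAI1, and in assembly GRCh38.p14 both SNAI1 and TRERNA1 lie on chromosome 20. The comparisons address which genes respond to each siRNA and how far the responses to both overlap. Log2 signals of arrays of 1 group correlated across probes at 0.994 to 0.995, and those of different groups at 0.989 to 0.992. No pair of arrays was a duplicate. The first principal component (38.1% of the variance) separated the controls from both knockdowns, and the second (32.7%) separated the knockdowns from each other.

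The targeted genes could not be checked on these arrays. The SNAI1 probe read 127 and 127 with Snai1 siRNA, 143 and 144 with control siRNA, and 138.8 and 146.5 with ncRNA-a7 siRNA, at percentiles 15.9 to 48.0 of each array. It lay in the dim part left out by the filter, and its difference from control was not called over all probes with Snai1 siRNA (limma adjusted p = 0.479) or ncRNA-a7 siRNA (adjusted p = 0.997). The TRERNA1 probe read 143 and 129 with Snai1 siRNA, 118 and 118 with control siRNA, and 130 and 132 with ncRNA-a7 siRNA, at percentiles 3.95 to 39.5. Neither probe was bright enough for a fold change, so the arrays do not show whether either target fell.

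With Snai1 siRNA, the largest rises over control were in CIDEC, a lipid droplet protein (11.6-fold, log2 change 3.53 ± 0.12 SE, limma adjusted p = 2.1e-08, n = 2 per group), CLDN2, a tight junction claudin (7.91-fold, adjusted p = 7.26e-08), and PPARG, a nuclear receptor of lipid metabolism (4.33-fold, adjusted p = 3.1e-06). The integrin subunit ITGB4 rose 3.53-fold and CEMIP, a hyaluronan-binding protein, 3.40-fold. LRRC26, LBP, REEP1, SCD5 and STK39 rose 3.11-fold to 3.32-fold. The largest falls were in the secreted glycoprotein STC2 (3.65-fold lower, log2 change -1.87 ± 0.12 SE, limma adjusted p = 9.48e-06), the Ras-like protein RASD1 (3.24-fold lower), the imprinted noncoding RNA H19 (2.99-fold lower) and the nuclear receptor NR4A2 (2.84-fold lower). DIRAS3, UHMK1, LXN, HORMAD1, TERF1 and DTD2 were 2.53-fold to 2.69-fold lower. A second CIDEC probe rose by a log2 change of 1.00, and of 3 further PPARG probes 1 rose by 2.30 and 2 were too dim to pass the filter.

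Of 19730 features, limma called 1807 with Snai1 siRNA (963 higher, 844 lower, Benjamini-Hochberg), 133 of them at least 2-fold. With median scaling 359 were called higher and 705 lower, a share of 33.7% higher against 53.3%. Left-out arrays lowered the count to 1051 without Snai1 siRNA replicate 1, 674 without Snai1 siRNA replicate 2, 457 without control siRNA replicate 1 and 701 without control siRNA replicate 2.

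**Figure D1:**
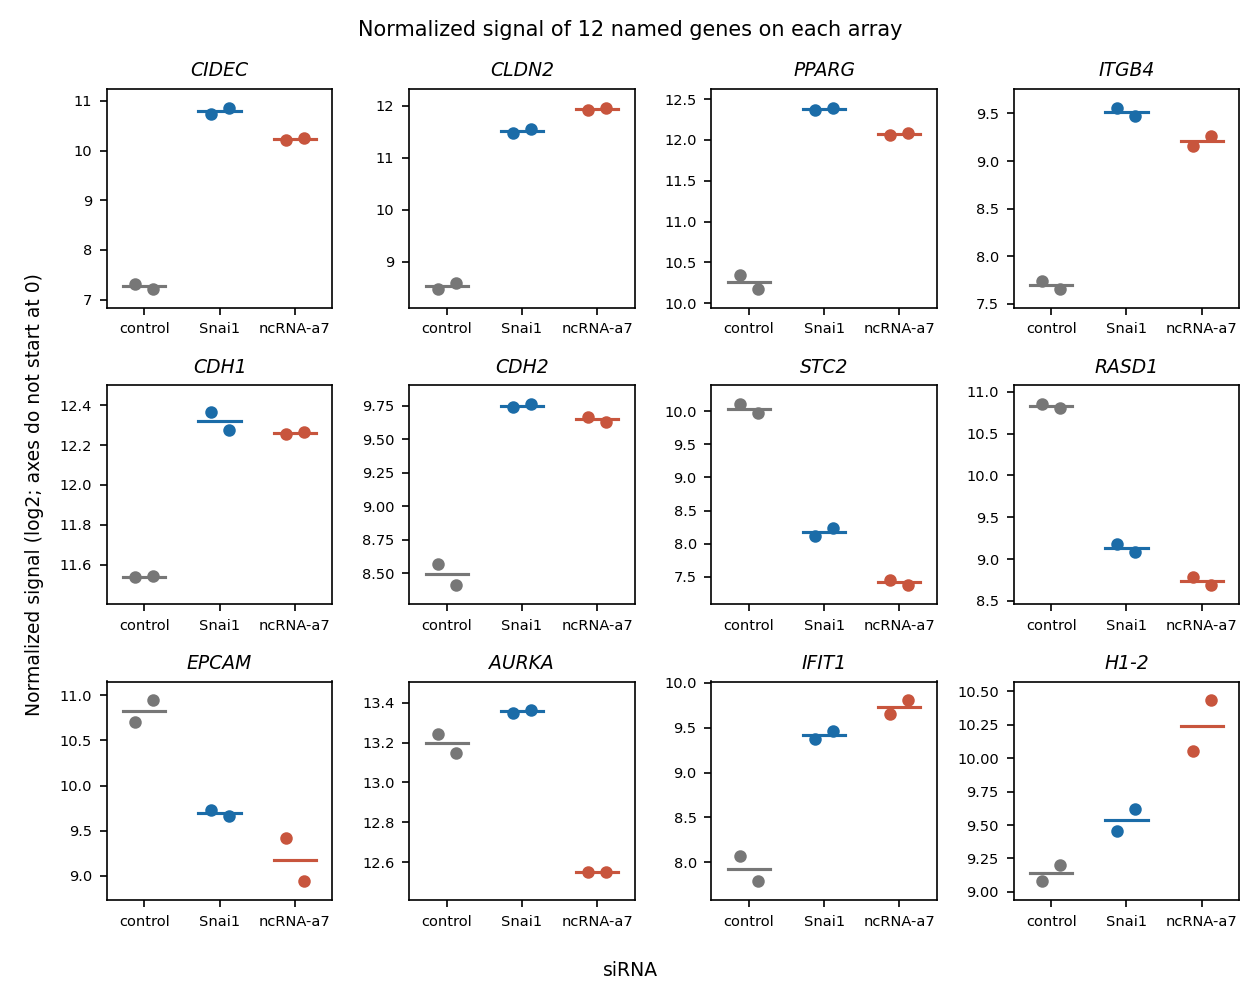
Normalized log2 signal of 12 named genes on each array (points) with the group mean (line), for control, Snai1 and ncRNA-a7 siRNA, 2 arrays each. CIDEC and CLDN2 lay above control with both siRNAs by log2 changes of 2.96 to 3.53, STC2 differed by -1.87 and -2.63, and AURKA was lower with ncRNA-a7 siRNA.

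CDH1, which encodes E-cadherin, rose 1.72-fold with Snai1 siRNA (log2 change 0.78 ± 0.11 SE, limma adjusted p = 0.0014), while VIM, which encodes vimentin, differed by 0.06 ± 0.11 (adjusted p = 0.796) and AURKA, a mitotic kinase, by 0.16 ± 0.11 (adjusted p = 0.434). Under median scaling the differences of VIM and AURKA turned negative, at -0.05 and -0.01. Among 20 epithelial junction and keratin genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), with PKP2 2.67-fold higher, EPCAM 2.18-fold lower and CRB3 1.53-fold lower. The CRB3 call was lost without Snai1 siRNA replicate 1, Snai1 siRNA replicate 2 or control siRNA replicate 1 (highest adjusted p = 0.244), and with an offset of 16, no filter or the mean of a gene's probes. Among 10 genes reported as repressed by SNAI1, CDH1 rose and CRB3 fell (2 and 1 adjusted over the list alone), and 0 of 9 other EMT transcription factors were called.

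Migration and adhesion genes were called higher as a group with Snai1 siRNA (limma camera adjusted p = 4.8e-08, and adjusted p = 0.129 with an estimated correlation). Of 40 members 15 rose and 0 fell (19 and 2 adjusted over the list alone), among them ITGB4, the metalloproteinase inhibitor TIMP2 (2.39-fold) and the integrin subunit ITGA3 (1.92-fold). Of 25 mesenchymal marker genes 7 rose and 1 fell (9 and 2 adjusted over the list alone). PLAU, the urokinase protease, rose 2.90-fold, CDH2, which encodes N-cadherin, 2.40-fold and the receptor kinase AXL 2.09-fold, and THBS1 fell by 0.77 on the log2 scale. The mesenchymal list was called up by camera (adjusted p = 0.0224, and adjusted p = 0.638 with an estimated correlation). That call was lost with an offset of 16 (adjusted p = 0.0575) and without ncRNA-a7 siRNA replicate 2 (adjusted p = 0.0655).

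The remaining 20 lists were not called by camera in this comparison (limma adjusted p from 0.131 to 0.971). Of 32 unfolded protein and ATF4 response genes 4 rose and 10 fell (5 and 10 adjusted over the list alone), with ASNS, asparagine synthetase, 1.94-fold lower and ATF3 1.89-fold lower. Of 28 hypoxia and glycolysis genes 4 rose and 3 fell (5 and 3 adjusted over the list alone), with EGLN3 1.67-fold higher and ADM 1.78-fold lower. Of 25 NRF2 target genes 4 rose and 2 fell (4 and 3 adjusted over the list alone), with ALDH3A1 1.77-fold higher and SRXN1 2.04-fold lower. Of 24 p53 target genes 2 rose and 3 fell (4 and 3 adjusted over the list alone), with GDF15 1.86-fold lower. Of 29 interferon response genes 3 rose and 0 fell, with IFIT1 2.80-fold higher. Of 29 G1/S genes 2 rose and 1 fell, with TYMS 1.92-fold higher and RRM2 1.75-fold lower. Of 46 G2/M genes 1 rose and 1 fell, of 22 cholesterol synthesis genes 1 rose and 2 fell, and of 17 TGF-beta response genes 1 rose and 1 fell. For these 5 lists the counts were equal when adjusted over the list alone. Of 21 NF-kappaB and cytokine genes 1 rose and 0 fell (2 and 3 adjusted over the list alone).

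Of 22 genes near SNAI1 on chromosome 20, 1 fell with Snai1 siRNA, and of 59 ribosomal protein genes 2 fell, RPL28 being 1.81-fold lower. No member of the 10 histone or the 9 lung epithelial genes was called. Among markers of other cell types, 2 of 5 fibroblast genes, 1 of 5 leukocyte genes (CD14, 2.22-fold) and 1 of 5 endothelial genes (ESAM, 2.79-fold) rose. Adjusted over the list alone the counts of these lists were equal, except for 2 leukocyte genes. The median and the tested direction of the EMT transcription factor, leukocyte and endothelial lists differed in sign, and so did the mean and the tested direction of the p53 list. Fry, which compares a list with no other genes, gave an adjusted p under 0.05 for 6 lists with Snai1 siRNA, both lists called by camera among them. The other 4 were the G1/S (fry adjusted p = 0.0128) and hypoxia lists (0.0354), on balance higher, and the unfolded protein and ATF4 (0.0354) and ribosomal lists (0.0128), on balance lower.

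With ncRNA-a7 siRNA, CLDN2 rose 10.6-fold over control (log2 change 3.41 ± 0.12 SE, limma adjusted p = 3.06e-08, n = 2 per group), CIDEC 7.80-fold (adjusted p = 8.28e-08) and CEMIP 5.03-fold (adjusted p = 9.57e-06). The small GTPase RAB37 rose 4.92-fold, DPY19L1 3.74-fold, PPARG 3.51-fold and the interferon-induced IFIT1 3.48-fold. SLC51B rose 3.12-fold and MORC4 3.02-fold. CEACAM1 rose by a log2 change of 1.66, and its other probes changed by 1.00 and 0.56. Its change was 0.99 without Snai1 siRNA replicate 1 and 0.88 without ncRNA-a7 siRNA replicate 1. The representing probe was chosen anew in each fit, so these lower values may come from another of its probes. STC2 was 6.19-fold lower (log2 change -2.63 ± 0.12 SE, limma adjusted p = 2.82e-07), RASD1 4.26-fold lower, NR4A2 3.55-fold lower and EPCAM, an epithelial adhesion molecule, 3.12-fold lower. DIRAS3, PSAT1, ID4, ULBP1, SLC2A3 and TOR1AIP2 were 2.63-fold to 2.91-fold lower. The second CIDEC probe rose by a log2 change of 0.62.

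Limma called 1962 features with ncRNA-a7 siRNA (1141 higher, 821 lower, Benjamini-Hochberg), 144 of them at least 2-fold. Left-out arrays lowered the count to 552 without control siRNA replicate 1, 673 without control siRNA replicate 2, 1017 without ncRNA-a7 siRNA replicate 1 and 1140 without ncRNA-a7 siRNA replicate 2. With median scaling 920 were called, 450 higher and 470 lower, a share of 48.9% higher against 58.2%.

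AURKA was 1.56-fold lower with ncRNA-a7 siRNA (log2 change -0.65 ± 0.11 SE, limma adjusted p = 0.00406), and its second probe changed by -0.69. The AURKA call was lost without control siRNA replicate 1 (log2 change -0.59, adjusted p = 0.0628). CDH1 rose 1.65-fold (adjusted p = 0.00194), and VIM differed by 0.34 ± 0.11 (adjusted p = 0.0804). VIM was called without background correction, over the probes brighter than 75% of all probes and with a trended variance prior. Of 20 epithelial genes 3 rose and 3 fell (3 and 4 adjusted over the list alone), with PKP2 1.92-fold higher and CRB3 1.84-fold lower, a CRB3 call lost without control siRNA replicate 1 (adjusted p = 0.0578). Of 10 genes reported as repressed by SNAI1 1 rose and 2 fell, and 0 of 9 EMT transcription factors were called, with equal counts adjusted over the list alone.

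Mesenchymal marker genes were called higher as a group with ncRNA-a7 siRNA (limma camera adjusted p = 1.25e-05, and adjusted p = 0.195 with an estimated correlation), with 10 of 25 higher and 0 lower (13 and 0 adjusted over the list alone). PLAU rose 2.51-fold, CDH2 2.23-fold and AXL 2.07-fold. Of 40 migration and adhesion genes 12 rose and 0 fell (18 and 0 adjusted over the list alone), with ITGB4 2.85-fold, ITGA3 2.33-fold and TIMP2 1.99-fold higher (camera adjusted p = 4.67e-07, and adjusted p = 0.155 with an estimated correlation).

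Interferon response genes were also called higher as a group with ncRNA-a7 siRNA (limma camera adjusted p = 3.85e-05, and adjusted p = 0.234 with an estimated correlation), with 9 of 29 higher and 0 lower (12 and 0 adjusted over the list alone). IFIT1 led, IFI6 rose 2.75-fold and the helicase DDX60 1.75-fold. The IFI6 call was lost with a trended variance prior and without control siRNA replicate 1 (adjusted p = 0.0503). Of 10 replication-dependent histone genes 6 rose and 0 fell (7 and 0 adjusted over the list alone), with H1-2 2.15-fold, H2BC5 1.96-fold and H2AC18 1.83-fold higher. The histone list was called by camera (adjusted p = 0.000516, and adjusted p = 0.195 with an estimated correlation). Histone genes have near-identical copies, so which copy a probe measured is uncertain.

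Unfolded protein and ATF4 response genes were called lower with ncRNA-a7 siRNA (limma camera adjusted p = 0.00359, and adjusted p = 0.234 with an estimated correlation). Of 32 members 5 rose and 11 fell (5 and 12 adjusted over the list alone). Those that fell include PSAT1, an enzyme of serine synthesis (2.90-fold lower), ASNS (2.41-fold lower) and MTHFD2, a mitochondrial folate enzyme (2.35-fold lower). Those that rose include CALR and CRELD2, proteins of the endoplasmic reticulum, with log2 changes of 0.60 and 0.62. The list of 29 G1/S and DNA replication genes was called lower (camera adjusted p = 0.0406, and adjusted p = 0.234 with an estimated correlation), with 1 member higher and 3 lower, equal adjusted over the list alone. TYMS rose 1.59-fold and RFC3 was 1.71-fold lower. The TYMS call was lost with median scaling, and the RFC3 call without control siRNA replicate 1 (adjusted p = 0.0561). The list call was lost over the probes brighter than 75% of all probes (adjusted p = 0.0906) and without control siRNA replicate 1 (0.0551), control siRNA replicate 2 (0.0707), ncRNA-a7 siRNA replicate 1 (0.0545) or ncRNA-a7 siRNA replicate 2 (0.126).

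The remaining 16 lists were not called by camera with ncRNA-a7 siRNA (limma adjusted p from 0.101 to 0.989). AURKA was the 1 called member of 46 G2/M genes. Of 17 TGF-beta response genes 5 rose and 2 fell (5 and 4 adjusted over the list alone), with CCN2 1.81-fold and SMAD6 1.79-fold higher. Of 25 NRF2 target genes 5 rose and 2 fell (6 and 3 adjusted over the list alone), with the transporter ABCC3 2.58-fold and ALDH3A1 1.98-fold higher. Of 28 hypoxia and glycolysis genes 4 rose and 1 fell (5 and 1 adjusted over the list alone), with EGLN3 1.76-fold higher. Of 21 NF-kappaB and cytokine genes 1 rose and 1 fell (2 and 3 adjusted over the list alone). Of 24 p53 target genes 1 rose, and of 22 cholesterol synthesis genes 1 rose and 1 fell. Of 22 genes near SNAI1 2 fell, PTPN1 by 0.52 and DDX27 by 0.56 on the log2 scale. Both calls were lost without control siRNA replicate 1, control siRNA replicate 2 or ncRNA-a7 siRNA replicate 1, and the PTPN1 call also without Snai1 siRNA replicate 2 (highest adjusted p of either gene = 0.231). Both were also lost with an offset of 16 or no filter. Of 59 ribosomal protein genes 1 rose and 4 fell, with RPS7 2.08-fold lower. Ribosomal protein genes have many near-identical copies, so these values are uncertain.

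Of 9 lung epithelial genes 1 rose with ncRNA-a7 siRNA, and 0 of 5 fibroblast markers were called. CD14 (2.01-fold) and ITGAM (1.74-fold) rose among 5 leukocyte markers, and 1 endothelial marker of 5 rose and 1 fell. Adjusted over the list alone, the counts of the G2/M, p53, cholesterol, chromosome 20, ribosomal, lung, fibroblast, leukocyte and endothelial lists were equal. The median and mean of the TGF-beta, NRF2, hypoxia, lung, leukocyte and endothelial lists differed in sign. Fry gave an adjusted p under 0.05 for 11 lists with ncRNA-a7 siRNA, the 6 called by camera among them. The other 5 were the TGF-beta (fry adjusted p = 0.0126), p53 (0.0202) and leukocyte lists (0.0202), on balance higher, and the lists of genes near SNAI1 (0.0355) and of ribosomal proteins (0.00343), on balance lower.

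**Figure D2:**
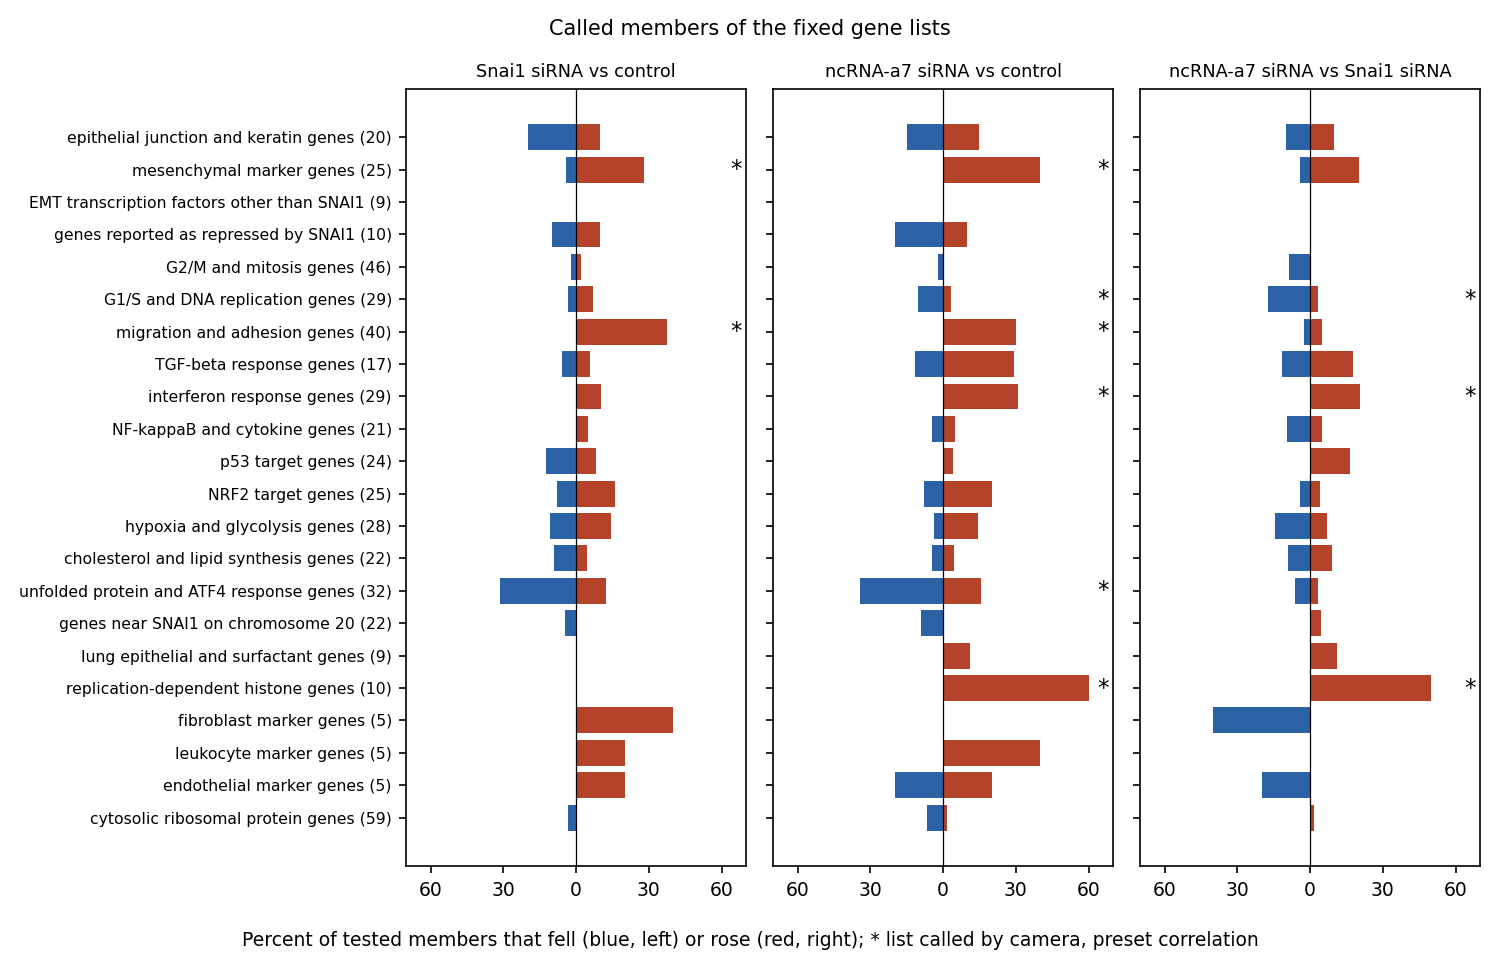
Percent of tested members of each fixed gene list that limma called higher (red, right) or lower (blue, left) in each comparison, with the number tested in parentheses and an asterisk for lists called by camera with the preset correlation, of which 0 were called with an estimated correlation. With ncRNA-a7 siRNA 6 of 10 histone genes rose, and with Snai1 siRNA 15 of 40 migration and adhesion genes rose.

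Compared directly, KRT80, an epithelial keratin, was 3.49-fold higher with ncRNA-a7 siRNA than with Snai1 siRNA (log2 difference 1.80 ± 0.14 SE, limma adjusted p = 6.2e-05, n = 2 per group), and S100A10, an annexin-binding protein, 3.38-fold higher (adjusted p = 6.2e-05). UROD and B4GALT7 were 2.93-fold higher and RAB37 2.91-fold higher. PAFAH1B1, PRTFDC1, KCNJ16, NETO2 and ARHGAP26 were 2.60-fold to 2.77-fold higher. TOR1AIP2 was 3.07-fold lower (log2 difference -1.62 ± 0.12 SE, adjusted p = 6.2e-05), the heparan sulfate proteoglycan SDC4 lower by a log2 difference of -1.59 and the translation repressor EIF4EBP2 2.90-fold lower. LRRC26, RBBP4, CELF1, COQ8A, GXYLT1, PPP2R5A and NEMP1 were 2.19-fold to 2.85-fold lower. AURKA was 1.75-fold lower with ncRNA-a7 siRNA than with Snai1 siRNA (log2 difference -0.81 ± 0.11 SE, adjusted p = 0.00188). CDH1 differed by -0.06 ± 0.11 (adjusted p = 0.811) and VIM by 0.28 ± 0.11 (adjusted p = 0.162), and VIM was called with a trended variance prior.

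Limma called 1601 features between the siRNAs (935 higher and 666 lower with ncRNA-a7 siRNA, Benjamini-Hochberg), 85 of them at least 2-fold. With median scaling 70.6% of calls were higher, against 58.4%. Left-out arrays lowered the count to 740 without Snai1 siRNA replicate 1, 352 without Snai1 siRNA replicate 2, 980 without control siRNA replicate 1, 615 without ncRNA-a7 siRNA replicate 1 and 935 without ncRNA-a7 siRNA replicate 2.

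Histone genes were higher with ncRNA-a7 siRNA than with Snai1 siRNA in 5 of 10 members and lower in 0 (6 and 1 adjusted over the list alone), with H2BC5 2.00-fold and H2AC6 1.97-fold higher (limma camera adjusted p = 0.0034, and adjusted p = 0.318 with an estimated correlation). Of 29 interferon response genes 6 were higher and 0 lower (7 and 1 adjusted over the list alone), with OAS3 1.68-fold and HERC6 1.53-fold higher (camera adjusted p = 0.0127, and adjusted p = 0.506 with an estimated correlation). The OAS3 call was lost without Snai1 siRNA replicate 2 and the HERC6 call without Snai1 siRNA replicate 2 or ncRNA-a7 siRNA replicate 1 (highest adjusted p = 0.0653 and 0.0688). The interferon list lost its call over the probes brighter than 75% of all probes (adjusted p = 0.148) and without ncRNA-a7 siRNA replicate 2 (adjusted p = 0.208). Of 29 G1/S genes 1 was higher and 5 lower (1 and 7 adjusted over the list alone). The list was called lower (camera adjusted p = 0.00349, and adjusted p = 0.318 with an estimated correlation). SLBP, the histone mRNA binding protein, was called higher with Snai1 siRNA than with control. That call was lost with median scaling, an offset of 16 or no filter. Between the siRNAs SLBP was 1.64-fold lower with ncRNA-a7 siRNA. The SLBP call was lost with an offset of 16 and without Snai1 siRNA replicate 1, Snai1 siRNA replicate 2 or ncRNA-a7 siRNA replicate 1 (highest adjusted p = 0.0742).

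The remaining 19 lists were not called by camera between the siRNAs (limma adjusted p from 0.144 to 0.995). Of 25 mesenchymal genes 5 were higher and 1 lower (6 and 1 adjusted over the list alone), with CCN2 1.94-fold and LGALS1 1.71-fold higher and COL4A1 1.75-fold lower. Of 40 migration and adhesion genes 2 were higher and 1 lower, with CAPN2 2.35-fold higher. Of 20 epithelial genes 2 were higher and 2 lower (2 and 4 adjusted over the list alone), with KRT7 1.62-fold higher. Of 46 G2/M genes 0 were higher and 4 lower. Of 32 unfolded protein and ATF4 response genes 1 was higher and 2 lower (1 and 4 adjusted over the list alone), with MTHFD2 1.65-fold lower. Of 17 TGF-beta genes 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with SMAD6 1.74-fold higher. Of 24 p53 target genes 4 were higher and 0 lower (4 and 1 adjusted over the list alone). Of 28 hypoxia genes 2 were higher and 4 lower (3 and 4 adjusted over the list alone). Of 22 cholesterol synthesis genes 2 were higher and 2 lower (3 and 3 adjusted over the list alone), with SC5D 1.84-fold higher.

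Among the other lists, 1 of 21 NF-kappaB genes was higher and 2 lower with ncRNA-a7 siRNA, with CCL20 1.73-fold lower. Of 25 NRF2 target genes 1 was higher and 1 lower. PEDS1, 1 of 22 genes near SNAI1, was 1.71-fold higher, and 1 of 59 ribosomal and 1 of 9 lung epithelial genes were higher. Of 5 fibroblast markers 2 were lower and of 5 endothelial markers ESAM was 1.77-fold lower. No member was called among the 10 genes reported as repressed by SNAI1, the 9 EMT transcription factors and the 5 leukocyte markers. Adjusted over the list alone the counts of the lists without their own value were equal, except for 2 lung epithelial genes lower and 1 leukocyte gene higher. The median and the tested direction of the NF-kappaB, cholesterol and endothelial lists differed in sign. Fry gave an adjusted p under 0.05 for 6 lists between the siRNAs, the G1/S and histone lists among them, but not for the interferon list (fry adjusted p = 0.0821). The other 4 were the mesenchymal, TGF-beta and p53 lists, on balance higher with ncRNA-a7 siRNA, and the ribosomal list, on balance lower (fry adjusted p = 0.0315 for each).

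Changes with both siRNAs against the shared control arrays overlapped. Limma called 738 features in both in the same direction, 516 higher and 222 lower. Independent lists of these sizes would share 55.7 and 35.1. Both lists rest on the same control arrays and are not independent, so these values are no chance level for them. The highest of 100 simulated data sets without effect shared 1, a count that is low by construction because such data give hardly any calls. CIDEC, CLDN2, CEMIP, PPARG and ITGB4 led those that rose and STC2, RASD1, NR4A2, DIRAS3 and EPCAM those that fell. A further 23 were called in opposite directions, 6 of them higher with Snai1 siRNA. S100A10 changed by a log2 value of -1.10 with Snai1 siRNA and 0.66 with ncRNA-a7 siRNA, and SDC4 by 0.82 and -0.77. Of the 738 features, 73 (9.89%) were also called between the siRNAs.

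Log2 fold changes with both siRNAs correlated across features with a Pearson r of 0.555 and a Spearman rho of 0.481, where features are not independent replicates. Data without effect gave a mean Pearson r of 0.50, and no such value was computed for rho. The changes had the same sign in 66.75% of features, against 66.70% with no effect. Over all features, agreement in sign was thus no greater than shared controls alone gave. The covariance was 0.0432, against 0.00875 with no effect. With a different control array for each siRNA, r was 0.375 and 0.416. No array is shared in this form, so the no-effect r of 0.50 does not apply to it. Independent noise of the arrays alone would give no correlation here, though no such value was simulated. These r values thus do not come from the noise of a shared array. A difference common to both control arrays would remain in them. With 2 control arrays the controls cannot be split into separate sets with replicates, and part of the excess in the r of 0.555 and in the covariance may come from the shared controls. Without control siRNA replicate 1 the number called in both was 189, without control siRNA replicate 2 it was 268, without Snai1 siRNA replicate 1 it was 483 and without Snai1 siRNA replicate 2 it was 350.

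**Figure D3:**
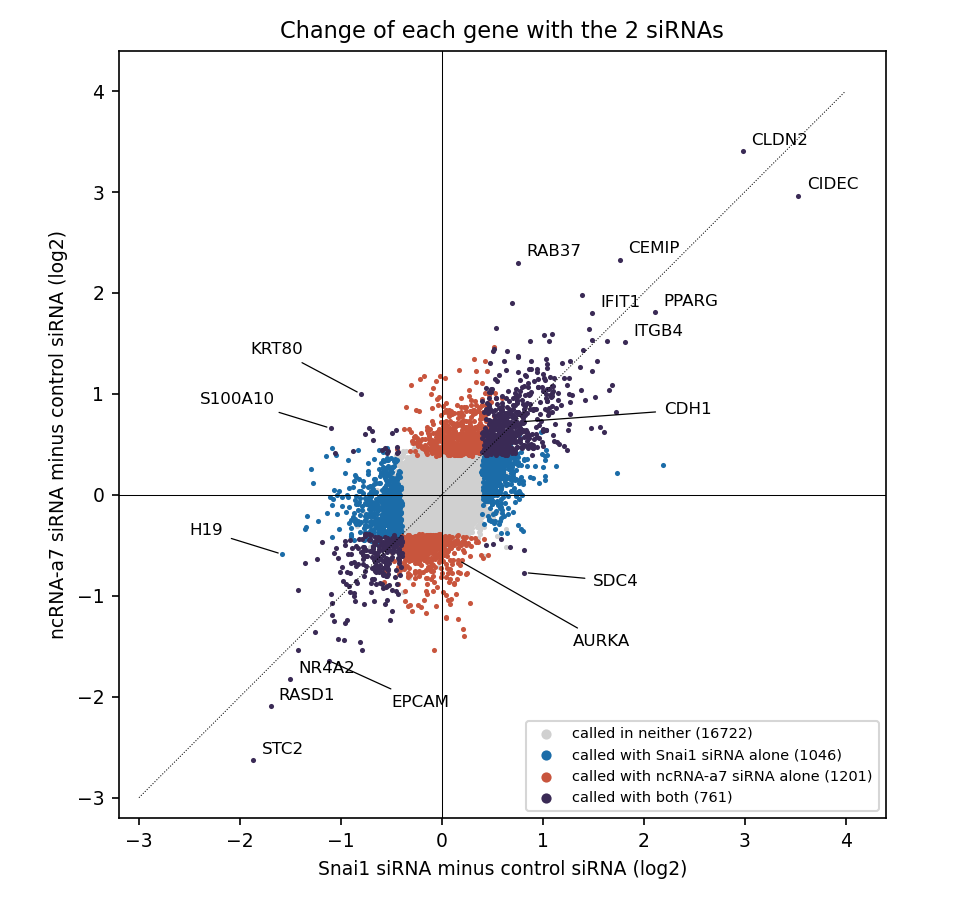
Log2 change of each of 19730 features with Snai1 siRNA (horizontal axis) and ncRNA-a7 siRNA (vertical axis) against control siRNA, coloured by the comparison in which limma called it, with equal changes on the dotted line. STC2, RASD1 and NR4A2 lie at the lower left and CLDN2, CIDEC, CEMIP and PPARG at the upper right, and KRT80, S100A10 and SDC4 lie where the signs differ.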

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

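The comparisons between siRNAs, made with limma and camera, the fits with other scalings or without an array, and the test of chromosome 20 genes were planned. The other tests in this part, and the use of those fits to weigh the interferon result, were chosen after the result was seen. The siRNAs differed in AURKA, with a log2 difference of -0.81 between ncRNA-a7 siRNA and Snai1 siRNA. The list medians of G1/S and DNA replication genes differed by -0.20, of interferon response genes by 0.17 and of replication-dependent histone genes by 0.54, each called by camera with the preset correlation, but not with an estimated one (adjusted p = 0.318, 0.506 and 0.318). The interferon difference was not called by fry (adjusted p = 0.0821). A total of 23 features were called in opposite directions against control, KRT80, S100A10, SDC4, PAFAH1B1 and ARHGAP26 having the largest differences. All 23 were also called between the siRNAs, which follows almost by construction from opposite calls against the same controls and adds no support.

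The genes changed alike by both siRNAs were 738, against a highest count of 1 in simulated data without effect. Those data held independent noise and no effect of either siRNA, so hardly any feature could be called in both. The comparison therefore cannot decide how many of the 738 arose from chance values shared through the control arrays. The count was 189 without control siRNA replicate 1, 268 without control siRNA replicate 2, 483 without Snai1 siRNA replicate 1 and 350 without Snai1 siRNA replicate 2. Of the 738, 73 (9.89%) were also called between the siRNAs, against 8.11% of all features. The difference between the siRNAs over its standard error, squared, had a mean of 4.76 in these genes. It was 0.757 to 0.964 in 50 data sets simulated with independent noise and shifted controls alone. Noise of real arrays need not be independent between features, so the simulated range is no bound for the observed mean. Within the spread of these arrays, the 73 calls argue against the siRNAs acting alike in all of the 738. Neither value decides whether the control arrays stand apart, since the siRNAs may then still differ in some genes. It stays open whether the change shared by both siRNAs reflects the control arrays standing apart, since there was 1 control siRNA group and no untreated group. The 90.1% of the 738 without a call between the siRNAs do not decide this either. A lower SNAI1 level with both siRNAs may also underlie it, but the probe was too dim to tell (log2 change -0.0021 with ncRNA-a7 siRNA).

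The fall of AURKA with ncRNA-a7 siRNA was seen with a second probe (log2 change -0.69 ± 0.14 SE), which argues against a single faulty probe. The AURKA call was lost without control siRNA replicate 1 (limma adjusted p = 0.0628). The other G2/M genes had a median change of -0.0591 and a lower quartile of -0.169, so a common fall of mitotic genes of that size was not seen. Of 368 chromosome 20 genes 18 were called lower, against 657 of 12678 others (odds ratio 0.941, 95% interval 0.548 to 1.52, two-sided Fisher exact p = 0.905), an interval that leaves a wider change on chromosome 20 open. A response of AURKA to ncRNA-a7 loss or an off-target effect of the siRNA may each be the cause, and with 1 siRNA group per target neither was tested.

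The rise of interferon response genes with ncRNA-a7 siRNA had a camera adjusted p of at most 3.9e-05 under the 3 other scalings and at most 0.00469 without any 1 array, but an adjusted p of 0.234 with an estimated correlation. Camera compares a list with all other genes, and a constant scaling of an array shifts both alike. The fits with other scalings can therefore hardly decide whether scaling plays a part. The fits without 1 array argue against a single array as the whole source of the call with the preset correlation. NF-kappaB and cytokine genes had a median change of -0.0448 and an upper quartile of 0.148, below the median of 0.28 of the interferon list. Without ncRNA-a7 siRNA replicate 2 the interferon median was 0.14 and that upper quartile 0.215, so a wider innate response that also raises NF-kappaB and cytokine genes stays open. An antiviral response to the siRNA duplex and an effect of ncRNA-a7 loss may each produce this, and with 1 siRNA group per target neither was tested.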

How the results depend on the processing

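No alternative was added after the data were seen. Counts of called features moved by over 1.5 times as follows, in the order Snai1 siRNA against control, ncRNA-a7 siRNA against control, between siRNAs and both knockdowns. Median scaling gave 1064, 920, 698 and 331, an offset of 16 gave 987, 1032, 569 and 387, no filter gave 820, 822, 498 and 308, and a minimum of 1.5-fold gave 857, 845, 697 and 318. A trended robust variance prior gave 2718 for Snai1 siRNA, 2574 between siRNAs and 1146 for both. Without background correction there were 2487 between siRNAs and 1129 for both, and over the probes brighter than 75% of all probes 2498 and 1174. The minimum fold lowers counts by its construction, and the cause of the other shifts was not tested. Leaving out 1 array gave 457 to 1943, 552 to 1790, 352 to 1154 and 189 to 508, fits that have fewer arrays. The correlation across features ran from 0.501 to 0.616 in those fits.

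With an estimated correlation 0 lists were called in any of the 3 comparisons, against 2, 6 and 3. The estimate lay below the preset 0.01 for the migration and adhesion (-0.0133), histone (-0.0898) and G1/S lists (-0.0322), which lost their calls too. A correlation above the preset therefore does not explain those losses, and the test with 3 degrees of freedom has little power. For the interferon (0.0955), unfolded protein and ATF4 (0.032) and mesenchymal lists (0.0133) the estimate lay above the preset. A higher correlation may have contributed to the calls lost by these lists. With an offset of 16 there was 1 list for Snai1 siRNA. Leaving out 1 array gave 1 to 2, 5 to 6 and 2 to 3 lists. The SNAI1 probe was too dim for a fold change, so its values show only how the processing moves a dim probe. With Snai1 siRNA its difference lay between -0.26 and -0.24 without 1 array, and was -0.06 with the authors' scaled values, -0.16 without background correction and -0.42 with an offset of 16, none of them called. With ncRNA-a7 siRNA it turned positive with the authors' scaled values (0.0505) and ran from -0.10 to 0.10 without 1 array, around a value near 0. Under median scaling AURKA and VIM with Snai1 siRNA turned to -0.0054 and -0.0518, neither called. Of 198 values of single genes, 35 lost their call with median scaling, 37 with an offset of 16, 40 without a filter, 17 with the mean of a gene's probes and 6 with the authors' scaled values. Leaving out each array in turn lost the call in 194 of 1188 such values. The 1188 values hold each gene once per array left out, also where that array belonged to neither group compared. Their share of losses is thus lower than the share of named calls lost without at least 1 array. That share was largest between the siRNAs. The changes of direction were those of AURKA and VIM. VIM gained a call under 3 settings with ncRNA-a7 siRNA. The median change of all features shifted by -0.0547 to 0.0494 under the 3 other scalings. Without detection p-values the distance of dim genes from background is unknown.

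The replicate numbers did not pair the arrays (r of replicate differences -0.07, 0.01 and -0.01). With the replicate block the counts were 1664, 1730, 1433 and 657, the 11 list calls were kept and 3 gene calls were lost.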

Other observations

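The hypotheses in this part came from the largest changes; their gene lists and camera tests were fixed before those lists were tested, but the requirement that a call also hold with an estimated correlation was added after the values were seen. PPARG and CIDEC, a lipid droplet protein gene that PPARG is known to regulate, rose with both siRNAs, and a candidate explanation is a wider PPARG programme. Of 31 other PPARG and lipid droplet genes 5 rose and 1 fell with Snai1 siRNA, and 3 rose and 2 fell with ncRNA-a7 siRNA. Limma's camera called the list up in both (adjusted p = 0.0288 and 0.0239 over 4 tests, medians 0.19 and 0.19), which met the criterion written beforehand. With an estimated correlation, a form of camera with little power here, the adjusted p was 0.389 in both. Under this stricter reading a wider programme stays open.

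NR4A2 and RASD1, genes that respond to hormones and cyclic AMP, fell with both siRNAs, which may reflect lower cyclic AMP signalling. Of 32 other immediate early and cyclic AMP response genes 5 rose and 6 fell with Snai1 siRNA and 3 rose and 4 fell with ncRNA-a7 siRNA, and the list was not called (camera adjusted p = 0.567 and 0.108). The arrays thus hold no call of a joint fall of those genes, and the test does not exclude a smaller one.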
